A study of Mus musculus with 4 samples.

How the data were processed

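RNA from dendritic cells, sorted as positive for CD11c, I-Ab and CD4 and negative for CD8, from the spleens of C57BL/6 Gpr183 heterozygous mice was sequenced by the authors, per the labels' protocols, at a stated purity above 99% and from 100 ng of RNA per library, with the Ovation RNA-seq System and an Illumina HiSeq. Mice had received PBS (100 uL) or SRBC (1000000000 cells) for 1 h, and there were 2 libraries of each. Whether the libraries kept strand is not given in the sources used here, so overlapping and antisense genes cannot be separated.

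The authors deposited FPKM values per gene locus and library, per the file headers. Per the submitters' processing notes, the tools were CASAVA, TopHat2 2.0.8b and Cufflinks 2.1.1 and the genome build was mm10. The gene annotation, the option by which Cufflinks scaled libraries, any masking of abundant RNAs and the read totals are not given in the sources used here. The authors' deposited table also held q-values (a p-value adjusted by the authors) of their cuffdiff comparison of control and immunized libraries, per the file headers; these were printed beside the fit made here and not used in it. Columns were assigned to groups by their names. The summed FPKM differed between libraries, from 377167 to 558016, so the scale between libraries is itself uncertain, and several rescalings were tried. FPKM divides by transcript length, which makes values of very short RNAs unstable, and an exact 0 can be a failed estimate: 56 tested loci were listed at 0 in at least 1 library. Such values are given per library and no fold is printed against a group at 0.

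The table held 30043 loci, of which 23657 had a gene name and 6386 had none. Named loci with FPKM of at least 1 in at least 2 of the 4 libraries were tested, 11020 in all, of which 366 carried several gene names and are reported as uncertain, since their reads cannot be assigned to a single gene. A symbol with several loci was represented, in the gene lists, by the locus with the highest mean. Fold changes and tests came from limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean-variance trend) on log2(FPKM + 1), comparing 2 SRBC with 2 PBS libraries with no covariates, two-sided, with Benjamini-Hochberg adjustment over the tested loci and a threshold of 0.05. The fit had 2 residual and 28.7 prior degrees of freedom, so most of the estimate of spread was shared across genes. With 2 libraries against 2 there are 3 splits, so no permutation test could reach the threshold. The median standard error of a log2 fold change was 0.26. Coordinates are 1-based and come from the GENCODE M21 annotation of GRCm38, the build also called mm10, by symbol; 151 of the 156 named genes were matched.

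In all 33 gene lists were fixed before the data were examined, with 796 members of which 785 were matched: programs of dendritic cells and of red cell handling, and markers of other cells that the sort could hold. They were tested with camera in limma at a preset inter-gene correlation of 0.01, adjusted over the lists; camera with an estimated correlation and fry were alternatives. fry asks whether the genes of a list move on balance one way and does not compare the list with other genes. A list needed 5 tested members. Genes named in the text follow a rule fixed at the same time: the sort and genotype genes Itgax, H2-Ab1, Cd4, Cd8a, Gpr183 and Ptprc; the 15 highest and 10 lowest log2 fold changes among called genes whose SRBC libraries both lay beyond both PBS libraries; in each list up to 4 tested members with the smallest p, with Ccr7, Cd40, Cd80, Cd83 and Cd86 added for maturation and Sirpa and Cd47 for their pathway; and the most abundant marker of each other cell type. Genes named outside it are said to have been chosen after their values were seen.

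Alternatives changed a single choice at a time: a pseudocount of 0.1 or 0.01, no filter on low values or a stricter minimum of 5, median-of-ratios, upper-quartile, quantile or TPM rescaling, other variance models, a 2-fold threshold, each library left out and the replicate number as a block. Where a library was left out, its group kept a lone library, which is assumed to vary like the other group. Inclusion of loci without a gene name, removal of loci listed at 0 and restriction to autosomes were added after seeing the data. The last kept 9646 of the 11020 loci and also dropped names without matched coordinates. The procedure was tested on simulated data of 11020 genes for the comparison of SRBC with PBS: of 50 genes each, it recovered 100% of those changed by 2 or -2 on the log2 scale, 68% of those raised by 1 and 34% of those lowered by 1, with 6 false calls among 10820 unchanged genes. In the simulated list test 3 of 3 shifted lists were called with the preset correlation, 0 of the unshifted lists, and 0 shifted lists with an estimated correlation. In both simulations genes varied independently of each other, with spreads drawn from the fitted prior. The simulations therefore do not test the error rate in the real lists, whose estimated correlations ran from -0.092 to 0.82. They also held no difference in scale between libraries and no trend with level, so the error rate over single genes in the real data was not tested either. Depth was estimated from the spacing of the lowest FPKM values of genes with a single annotated transcript of at least 2000 bp, using 156 to 181 genes per library, and covers counting precision only.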

Results

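Splenic CD4+ dendritic cells were profiled by RNA sequencing from mice that had received either phosphate-buffered saline (PBS) or sheep red blood cells (SRBC, 1000000000 cells) 1 h earlier. Dendritic cells are the antigen-presenting cells that start T cell responses, and the CD4+ subset lies in the spleen where blood-borne particles arrive. All mice were heterozygous for Gpr183, which encodes a receptor for oxysterols that positions these cells. The data held 4 libraries, 2 after PBS and 2 after SRBC, as FPKM (fragments per kilobase of transcript, scaled to library size). Summed FPKM was 410321 and 377167 in PBS libraries 1 and 2 and 509007 and 558016 in SRBC libraries 1 and 2. Read totals were not given in the sources used here. From the steps between the lowest values, depth was estimated at 9400000, 9050000, 10300000 and 8680000 fragments in the same order, so that an FPKM of 1 on a transcript of 2 kb stood for 17.4 to 20.6 fragments. Values below are mean FPKM ± SD with n = 2 libraries per group, and log2 fold changes are SRBC minus PBS on the log2(FPKM + 1) scale, which understates changes of scarce transcripts. The labels do not say whether the libraries of a group came from separate mice, so p-values measure only the spread between these libraries, which may be technical. No sex is labelled. Xist and Y-linked genes, given below, showed a male pattern in both PBS libraries and a female pattern in both SRBC libraries. Every difference after SRBC is therefore confounded with sex.

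The genes that define the sort were checked first. Itgax, which encodes CD11c, measured 196 ± 22.6 after PBS and 238 ± 21.9 after SRBC, and Cd4 measured 87.5 ± 1.25 and 86.1 ± 14.5. Cd8a, absent from the sorted subset, stood at 1.91 ± 1.01 and 2.44 ± 0.0238. None of these, nor Ptprc (CD45; 397 ± 43.8 and 295 ± 8.87), passed the limma test on the deposited scale (adjusted p from 0.21 to 0.94). Rescaling of the libraries changed this: Ptprc was called lower with upper-quartile, quantile or TPM rescaling (log2 fold change -0.42 as deposited, down to -1.01) and Cd4 after quantile normalization (-0.033 as deposited, -0.59). Itgax was not called under the rescalings, where its log2 fold change ran from -0.33 to 0.20. H2-Ab1, which encodes the I-Ab beta chain, went from 4172 ± 378 to 8329 ± 818 (log2 fold change 1.00 ± 0.35 SE, limma adjusted p = 0.042). That call was lost without either PBS library and after quantile normalization or rescaling to TPM, where its log2 fold change was as low as 0.38. It was also lost with no filter on low values, with the replicate block and with unnamed loci included. In the authors' deposited table the q of H2-Ab1 was 0.93. Gpr183 itself (chromosome 14, 121952551 to 121965195, GRCm38) rose 3.56-fold, from 20.3 ± 2.33 to 72.0 ± 1.75 (log2 fold change 1.78 ± 0.22 SE, adjusted p = 2.4e-07). The authors' deposited table gave it a q of 0.10.

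Of 11020 named loci tested, 1488 were higher and 683 lower with limma at an adjusted p under 0.05, and 780 and 312 of these changed by at least 2-fold. The calls included Socs3, a feedback inhibitor of cytokine signalling, which rose 27.7-fold from 3.01 ± 1.80 to 83.5 ± 7.06 (log2 fold change 4.47 ± 0.26 SE, adjusted p = 4.1e-14). Stat5a, a transcription factor of cytokine receptors, rose 15.9-fold from 13.6 ± 1.29 to 217 ± 7.68. Il2ra, the alpha chain of the interleukin 2 receptor, went from 0.715 ± 0.0161 to 24.1 ± 0.0681, and Lrrc32, which anchors latent TGF-beta at the cell surface, from 0.362 ± 0.288 to 17.8 ± 0.498. Jdp2, an AP-1 family repressor, rose 26.0-fold, Zc3h12c, of a family of RNA-degrading regulators, rose 14.4-fold and the small GTPase gene Rab20 rose 38.8-fold. Mt2, a metallothionein, measured 0.939 and 0 after PBS and 20.6 and 31.3 after SRBC. In the other direction Zfp36l2, an mRNA decay factor, fell from 169 ± 17.3 to 33.3 ± 2.14 (log2 fold change -2.30 ± 0.22 SE, adjusted p = 1.4e-09), and Calhm2, a channel gene, from 30.5 ± 6.22 to 5.14 ± 0.447. Ddit4, an inhibitor of mTOR signalling, measured 37.0 and 92.6 after PBS and 9.94 and 11.3 after SRBC. Its log2 fold change was -2.36 and ranged from -3.01 to -1.71 when a library was left out.

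The balance of the calls depended on how libraries were scaled. Calls were 68.5% higher as deposited, 62.0% (1457 higher, 894 lower) with median-of-ratios rescaling, 49.8% (922 and 930) after quantile normalization, 41.9% (1022 and 1417) with upper-quartile rescaling and 27.6% (629 and 1648) with TPM. The median log2 fold change of tested loci moved from 0.070 as deposited to 0.0084, -0.039, -0.14 and -0.33 under these, so each direction below is relative to the deposited scale. Without SRBC library 1 the counts were 1154 and 273, and without SRBC library 2 they were 746 and 289. The SRBC and PBS libraries also differed in Xist and in Y-linked genes, as given with the sex-linked genes.

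**Figure D1:**
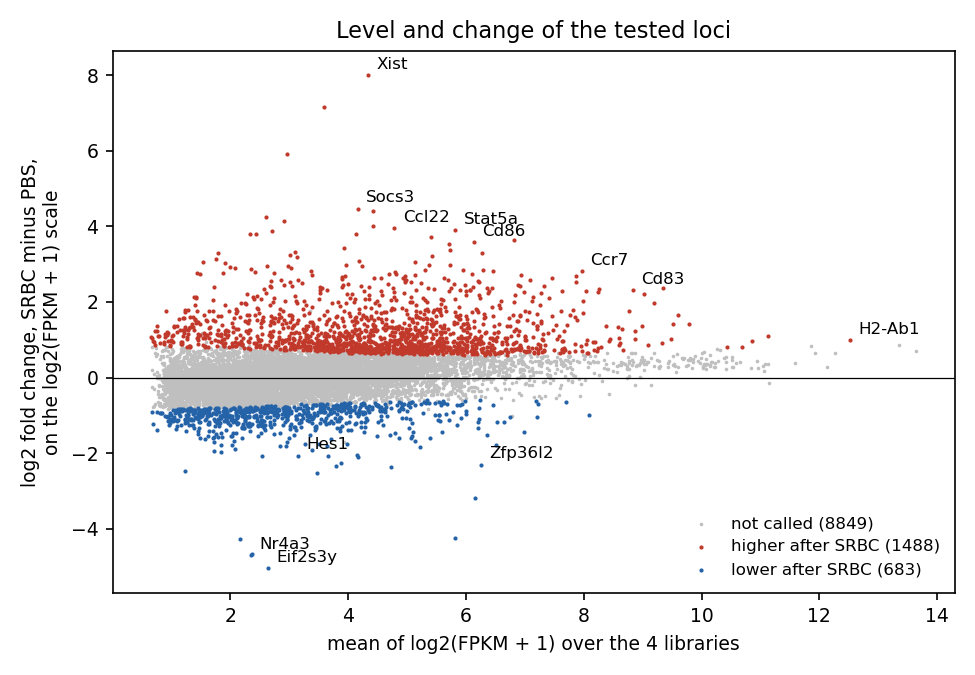
Each point is a named locus tested (11020), with the mean of log2(FPKM + 1) over the 4 libraries on the x axis and the log2 fold change, SRBC minus PBS, on the y axis. Red points (1488) were called higher and blue points (683) lower by limma, gray points (8849) were not called, and selected genes are labelled.

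In the list fixed for dendritic cell maturation, 25 of 37 measured loci were higher and 0 lower, with 26 and 1 adjusted over the list alone, and the median log2 fold change was 1.55. Cd86, a costimulatory ligand for CD28 (chromosome 16, 36603869 to 36666081), rose 12.5-fold from 19.4 ± 1.53 to 242 ± 32.2 (log2 fold change 3.57 ± 0.22 SE, adjusted p = 1.0e-13). Ccr7, the chemokine receptor that leads dendritic cells into T cell zones (chromosome 11, 99144196 to 99155077), rose 7.11-fold from 93.4 ± 5.53 to 664 ± 75.0. Cd40, Cd80 and Cd83 rose 5.00-fold, 4.07-fold and 5.00-fold, and Tnfsf9, the ligand of 4-1BB, rose 19.4-fold. With camera at a preset inter-gene correlation the adjusted p was 9.9e-19, and the adjusted p was 0.70 with an estimated correlation.

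Of 25 measured loci of NF-kB targets 21 were higher and 0 lower, and the same counts held adjusted over the list alone, with a median log2 fold change of 1.82. The inhibitor gene Tnip3 rose from 0.465 ± 0.199 to 19.3 ± 2.72, Gadd45b, a stress-response gene, from 31.4 ± 6.97 to 397 ± 25.3, Bcl2l1, which encodes the survival protein Bcl-xL, from 1.62 ± 0.238 to 23.6 ± 2.25, and Bcl3, an NF-kB cofactor, from 47.2 ± 6.80 to 312 ± 1.23. The camera adjusted p was 3.9e-22, with an adjusted p of 0.70 with an estimated correlation. NF-kB targets were also the list that fry called, with an adjusted p of 0.028.

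Among chemokines 11 of 14 measured loci were higher and 0 lower, as also adjusted over the list alone, or 5 and 0 after quantile normalization (median log2 fold change 1.36, or 0.80 without PBS library 2; camera adjusted p = 5.2e-08; adjusted p = 0.70 with an estimated correlation). Ccl22, a ligand of CCR4, rose 17.7-fold from 6.09 ± 1.47 to 108 ± 11.9, Cxcl10, a ligand of CXCR3, rose from 11.9 ± 0.953 to 75.9 ± 13.7 and Cxcl2 rose 7.20-fold. A locus named for both Ccl3 and Ccl4 measured 62.9 and 19.5 after PBS and 183 and 188 after SRBC. Its log2 fold change was 2.36, ranged from 1.54 to 3.18 when a library was left out, and its call was lost after quantile normalization. A locus named for Ccl3 alone, chosen after its values were seen, measured 158 and 30.0 after PBS and 188 and 208 after SRBC. Among cytokines 8 of 13 were higher and 0 lower, with 8 and 1 adjusted over the list alone and 6 and 1 after quantile normalization (median 1.16, camera adjusted p = 6.5e-04; adjusted p = 0.70 with an estimated correlation). Il1rn, the interleukin 1 receptor antagonist, rose 17.7-fold, Tnf 3.06-fold, Il1b 2.59-fold and Ebi3, a subunit of interleukins 27 and 35, 2.49-fold. The Tnf call was lost after quantile normalization.

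**Figure D2:**
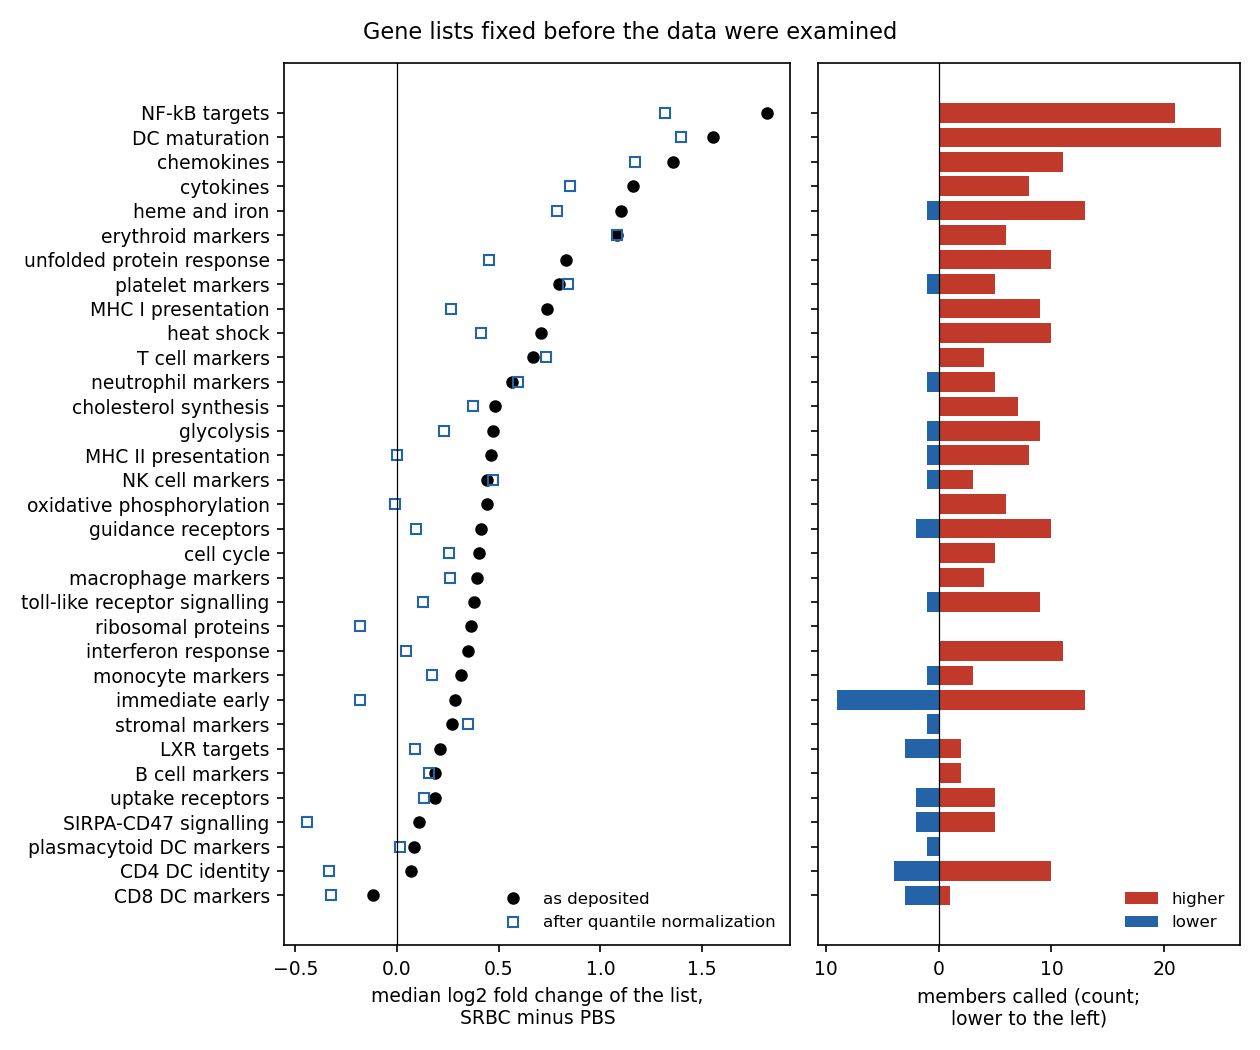
Left, the median log2 fold change (SRBC minus PBS) of each of the 33 gene lists, as deposited (black circles) and after quantile normalization (open blue squares); right, the count of members called higher (red) or lower (blue). NF-kB targets lie at 1.82 and 1.32, while ribosomal proteins lie at 0.37 and -0.18, so that their sign turns with the scaling.

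Genes of heme breakdown, iron handling and the NRF2 oxidative stress response were higher in 13 of 20 measured loci and lower in 1, or 14 and 1 adjusted over the list alone (median 1.10, camera adjusted p = 4.2e-09; adjusted p = 0.70 with an estimated correlation). Nfe2l2, which encodes NRF2, rose 10.2-fold from 23.8 ± 2.08 to 244 ± 47.5, and Srxn1, which repairs peroxiredoxins, from 0.511 and 0.401 to 8.98 and 11.1. Spic, a transcription factor of iron-recycling macrophages, rose 6.27-fold, Hmox1, which encodes the heme-degrading enzyme heme oxygenase 1, rose 5.23-fold and the locus of Txnrd1 and Eid3 rose 6.14-fold. The lower member, chosen after its values were seen, was Tfrc, the transferrin receptor (30.2 after PBS, 16.6 after SRBC). Among erythroid markers, a list of other cells that the sort could hold, 6 of 9 measured loci were higher and 0 lower, with 7 and 0 adjusted over the list alone (median 1.08, or 0.62 without SRBC library 2; camera adjusted p = 8.2e-04; adjusted p = 0.82 with an estimated correlation). The Hbb-b1 and Hbb-b2 locus measured 30.9 and 6.88 after PBS and 69.8 and 111 after SRBC, and that of Hba-a1 and Hba-a2 measured 29.2 and 3.17, then 36.1 and 69.0. Their log2 fold changes, 2.49 and 2.18, ranged from 1.48 to 3.50 and from 0.75 to 3.61 when a library was left out, and after quantile normalization 1 of the 9 loci was called. Both loci were higher in PBS library 1 than in PBS library 2, and in SRBC library 2 than in SRBC library 1. Most markers of B, plasmacytoid, NK and neutrophil cells, given below, showed the same order. Whether red cells in the sorted samples carried these transcripts was not tested. Both hemoglobin calls were also lost with no filter on low values and with a robust variance model. The Hba-a1 and Hba-a2 call was further lost with median-of-ratios or upper-quartile rescaling, the replicate block and unnamed loci included. Among macrophage markers 4 of 16 were higher and 0 lower, or 5 and 0 adjusted over the list alone. Their median was 0.39 (camera adjusted p = 0.025, or adjusted p = 0.82 with an estimated correlation). These 4 were Spic and Hmox1, which the heme list shares, Actn1 (18.9 ± 1.25 to 45.1 ± 3.87) and the locus of Cd68, Eif4a1 and Senp3, whose call was lost without PBS library 1. The macrophage list was not called with median-of-ratios rescaling, with the replicate block, without PBS library 2 (median 0.17) or without SRBC library 2 (0.20).

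In the unfolded protein response list 10 of 19 measured loci were higher and 0 lower, or 13 and 0 adjusted over the list alone and 7 and 1 after quantile normalization (median 0.83, camera adjusted p = 2.0e-05; adjusted p = 0.82 with an estimated correlation), with Hspa5, the chaperone BiP, rising 3.12-fold and Pdia6 2.53-fold. In the heat shock list 10 of 18 were higher and 0 lower, or 13 and 0 adjusted over the list alone and 3 and 0 after quantile normalization (median 0.71, camera adjusted p = 5.2e-05; adjusted p = 0.82 with an estimated correlation), with Hspa8 rising 2.67-fold, and the list was not called without PBS library 2. For MHC class I presentation 9 of 21 were higher and 0 lower, or 14 and 0 adjusted over the list alone and 3 and 0 after quantile normalization (median 0.74, camera adjusted p = 5.2e-05; adjusted p = 0.82 with an estimated correlation), with the proteasome activator gene Psme2 rising 2.37-fold. For MHC class II presentation 8 of 21 were higher and 1 lower, as also adjusted over the list alone (median 0.46, camera adjusted p = 0.031; adjusted p = 0.82 with an estimated correlation). Among these Lgmn, a lysosomal protease, rose 5.70-fold and Ifi30, a thiol reductase, 2.68-fold. The lower member, chosen after its values were seen, was March1, a ubiquitin ligase that removes class II from the surface (log2 fold change -1.11). The class II list was not called after quantile normalization, with 4 loci higher and 4 lower and an adjusted p of 0.75, nor with median-of-ratios rescaling, the stricter filter or the replicate block, nor without either PBS library. Its median was 0.27 without SRBC library 2.

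Glycolysis had 9 of 20 loci higher and 1 lower, as also adjusted over the list alone (median 0.47, camera adjusted p = 0.033; adjusted p = 0.82 with an estimated correlation). Pfkp, a phosphofructokinase gene, rose 4.44-fold and Aldoa 2.11-fold, while Pdk1, chosen after its values were seen, fell from 4.62 to 1.70. Cholesterol synthesis had 7 of 24 higher and 0 lower, or 11 and 0 adjusted over the list alone (median 0.48, camera adjusted p = 0.031; adjusted p = 0.82 with an estimated correlation), with Pmvk rising 2.56-fold. Oxidative phosphorylation had 6 of 27 higher and 0 lower, or 9 and 0 adjusted over the list alone (median 0.44, camera adjusted p = 0.0077; adjusted p = 0.82 with an estimated correlation). Ribosomal proteins were called as a list with 0 of 33 loci called, also 0 adjusted over the list alone (median 0.37, camera adjusted p = 0.037; adjusted p = 0.82 with an estimated correlation). After quantile normalization glycolysis had 4 loci higher and 2 lower, and oxidative phosphorylation and cell cycle had 0 called. The oxidative phosphorylation median was -0.0095 (adjusted p = 0.87) in that setting and the ribosomal median -0.18 (adjusted p = 0.034). The ribosomal median was 0.21 without SRBC library 2. Cell cycle genes had 5 of 28 higher and 0 lower, or 6 and 0 adjusted over the list alone (median 0.40, camera adjusted p = 0.036; adjusted p = 0.82 with an estimated correlation), among them Mki67 (30.2 ± 13.3 to 60.9 ± 11.0), whose call was lost without PBS library 1 or SRBC library 2. Without PBS library 1 the list's median was -0.0023 (adjusted p = 0.92), without PBS library 2 it was 0.74, and the list was not called without either SRBC library. The glycolysis call was likewise lost after quantile normalization and without PBS library 1, PBS library 2 or SRBC library 2, and the oxidative phosphorylation and ribosomal calls with TPM or without any of these 3 libraries. The cholesterol call was lost without PBS library 2, SRBC library 1 or SRBC library 2. Of the 2204 tested loci in the highest quintile of mean level, 690 were higher and 80 lower, with a median of 0.41. The medians of the oxidative phosphorylation, ribosomal, cell cycle and class II lists lay near that value. Camera set each list against all other tested loci, so these calls were not tested apart from the level of the genes.

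Interferon-stimulated genes were higher in 11 of 36 loci and lower in 0, as also adjusted over the list alone (median 0.35, camera adjusted p = 0.0082; adjusted p = 0.82 with an estimated correlation). Isg15, a ubiquitin-like protein, rose 2.67-fold, Isg20 (log2 fold change 1.54) and Oasl1 3.58-fold. The call was lost after quantile normalization (adjusted p = 0.075) and without SRBC library 2. Toll-like receptor signalling did not pass (adjusted p = 0.064), with 9 of 29 loci higher and 1 lower, or 9 and 2 adjusted over the list alone and 6 and 4 after quantile normalization. It passed with no filter on low values, with upper-quartile rescaling and with unnamed loci included, the last a setting chosen after seeing the data. Its higher members included Irak2, a kinase of the pathway (24.0 ± 2.45 to 85.5 ± 3.52), and Cd14 (2.74 ± 0.165 to 14.6 ± 4.41), and the lower was Tlr11.

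Immediate early genes went both ways, 13 of 33 loci being higher and 9 lower, or 14 and 10 adjusted over the list alone and 7 and 4 after quantile normalization, and the list did not pass (median 0.28, camera adjusted p = 0.20). Dusp5, a phosphatase of ERK, rose 6.79-fold and the locus of Dusp2 and Astl 7.11-fold. Nr4a3, a nuclear receptor gene, measured 35.3 and 17.8 after PBS and was listed at 0 in both SRBC libraries. The PBS libraries stood apart in this list: PBS library 1 exceeded PBS library 2 by a median of 1.26 on the log2 scale, and in 31 of the 33 loci. Fos, chosen after its values were seen, measured 415 and 104 after PBS and 78.2 and 73.0 after SRBC. Dusp6, also chosen after its values were seen, measured 17.4 and 21.1 after PBS and 4.12 and 4.61 after SRBC. Of the 9 lower calls 2, Nr4a3 and Dusp6, were kept without PBS library 1. The median of the list was 0.84 without PBS library 1 and -0.33 without PBS library 2, and it was called higher in the former case (adjusted p = 4.4e-08) and lower in the latter (adjusted p = 0.0012).

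Genes of CD4+ dendritic cell identity also went both ways, with 10 of 31 higher and 4 lower, the same adjusted over the list alone (median 0.067, camera adjusted p = 0.81). After quantile normalization 6 were higher and 10 lower, with a median of -0.33. Irf4, a transcription factor this subset needs, rose 4.40-fold from 66.8 ± 15.7 to 294 ± 31.7 and Rbpj, the DNA-binding partner of Notch, rose 2.38-fold. Hes1, a Notch target, fell from 20.6 and 14.1 to 3.52 and 3.14 (log2 fold change -2.06 ± 0.26 SE, adjusted p = 4.6e-07). Among guidance receptors and integrins 10 of 25 were higher and 2 lower, or 11 and 2 adjusted over the list alone and 4 and 1 after quantile normalization, without passing as a list (median 0.42, camera adjusted p = 0.054). These included Ccr7 and Gpr183, given above, and Gpr132, a receptor for oxidized lipids (114 ± 5.49 to 273 ± 2.39), while Gpr34 and Ccr2 were lower, the Ccr2 call being lost without either SRBC library. The guidance list passed without PBS library 1, without SRBC library 1, with upper-quartile or TPM rescaling and with no filter on low values. It also passed with unnamed loci included, loci listed at 0 left out or autosomes only, all chosen after seeing the data. Its median ran from 0.13 to 0.65 when a library was left out.

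The series title names missing CD47 on red cells as the signal that these dendritic cells survey, and CD47 is the ligand of SIRPA. Sirpa measured 165 ± 18.9 after PBS and 151 ± 6.16 after SRBC (log2 fold change -0.12 ± 0.22 SE, adjusted p = 0.75), and Cd47 118 ± 19.6 and 94.8 ± 9.84 (-0.31 ± 0.22 SE, adjusted p = 0.36). Both were called lower after quantile normalization (log2 fold changes -0.73 and -0.87), and Cd47 also with upper-quartile or TPM rescaling. In the list of this pathway 5 of 20 loci were higher and 2 lower, the same adjusted over the list alone, and it did not pass (adjusted p = 0.99, with a median of 0.11 although camera placed the list below other genes). After quantile normalization the list was called lower, with 2 loci higher and 9 lower, a median of -0.44 and an adjusted p of 0.0099. Grb2, an adaptor, rose 2.34-fold and Syk, a kinase, 1.94-fold, the latter call being lost after quantile normalization and with TPM. The locus of Sirpb1a, Sirpb1b and Gm9733, near-identical genes that may share reads, fell from 151 ± 30.3 to 66.0 ± 6.22. Uptake receptors did not pass as a list (5 of 22 higher and 2 lower, the same adjusted over the list alone, 3 and 2 after quantile normalization; median 0.19, adjusted p = 0.27), though Timd4, a receptor for phosphatidylserine, rose 10.8-fold from 2.01 ± 0.488 to 21.6 ± 4.12, and Scarb1 fell from 20.5 ± 0.703 to 9.16 ± 0.824. LXR targets had 2 of 15 loci higher and 3 lower, the same adjusted over the list alone (median 0.21, adjusted p = 0.71), with Scd1, a fatty acid desaturase, rising 5.72-fold and Cyp27a1, a sterol hydroxylase, falling from 67.2 ± 8.39 to 30.4 ± 4.85.

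**Figure D3:**
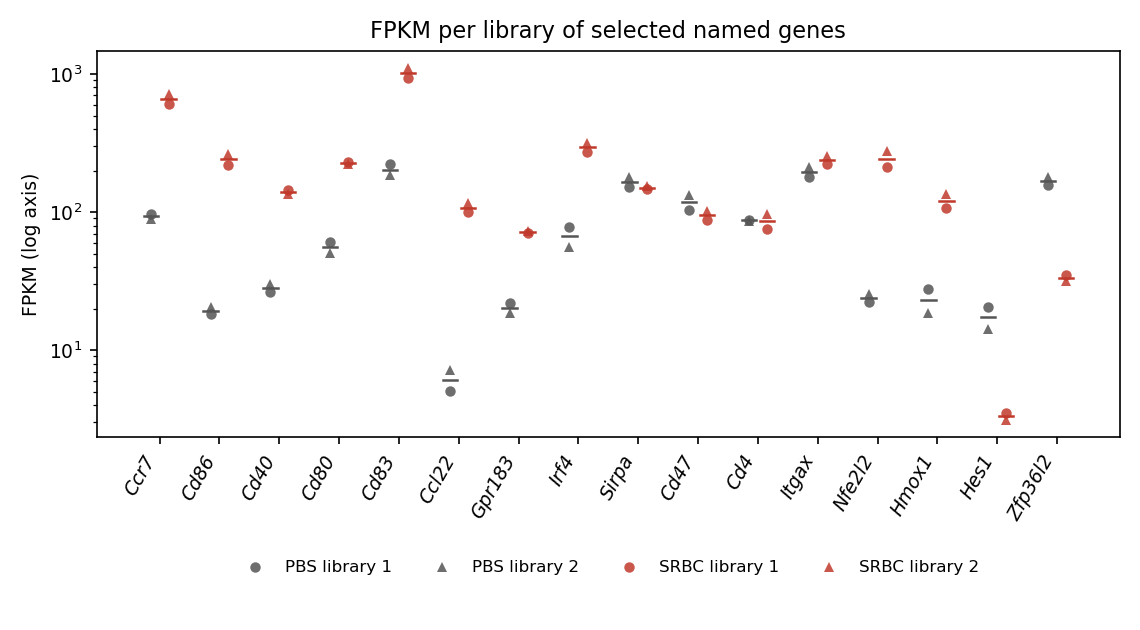
FPKM on a log axis of 16 named genes in each library (gray PBS, red SRBC; circles library 1, triangles library 2), with a short line at each group mean. Both SRBC libraries lie above both PBS libraries for Ccr7 (611 and 717 against 97.3 and 89.5) and Cd86, while Cd4 overlaps.

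Markers of other splenic cells were measured beside these groups. CD8+ dendritic cell markers had 1 of 14 loci higher, Ly75 (DEC-205, 6.98 ± 1.05 to 23.1 ± 0.240), and 3 lower, Clec9a, Batf3 and Tlr11, the same adjusted over the list alone (median -0.12, camera adjusted p = 0.18). The Clec9a and Batf3 calls were lost without either SRBC library. T cell markers had 4 of 9 higher and 0 lower (median 0.67, adjusted p = 0.11), neutrophil markers 5 of 14 and 1 (0.57, adjusted p = 0.077), platelet markers 5 of 8 and 1 (0.80, adjusted p = 0.082), monocyte markers 3 of 15 and 1 (0.31, adjusted p = 0.17), and NK cell markers 3 of 12 and 1 (0.44, adjusted p = 0.36). B cell markers had 2 of 18 higher and 0 lower (median 0.19, adjusted p = 0.71). Plasmacytoid dendritic cell markers had 0 of 16 higher and 1 lower (0.084, adjusted p = 0.93), and stromal markers 0 of 8 and 1 (0.27, adjusted p = 0.71), and for both of these camera pointed down while the median was above 0. Adjusted over the list alone, the higher and lower counts were 4 and 0 for T cells, 6 and 1 for neutrophils, 6 and 1 for platelets, 3 and 1 for monocytes, 3 and 1 for NK cells, 1 and 0 for B cells, 0 and 1 for plasmacytoid cells and 0 and 1 for stroma. After quantile normalization neutrophil markers had 2 loci higher and 1 lower, and platelet markers 3 and 0. When a library was left out, medians ran from 0.27 to 0.93 for T cells and 0.13 to 1.25 for neutrophils. They ran from 0.65 to 0.94 for platelets, -0.14 to 0.74 for monocytes, 0.022 to 0.91 for NK cells and -0.12 to 0.48 for B cells. Cd79a, a B cell receptor component, measured 9.27 and 3.39 after PBS and 5.63 and 14.9 after SRBC, and was called higher without PBS library 1 or SRBC library 1. The markers of B, plasmacytoid, NK and neutrophil cells were higher in PBS library 1 than in PBS library 2 in 47 of 60 loci, and higher in SRBC library 2 than in SRBC library 1 in 52 of 60. Of all 11020 tested loci 2970 and 7772 were higher in these directions. The pooled marker lists were chosen after the results were seen, and the other marker lists were left out of the pool. Without PBS library 1 the plasmacytoid, T cell, monocyte, neutrophil and NK lists were called higher, with adjusted p of 0.024, 0.024, 0.0055, 2.8e-07 and 0.0057. Without PBS library 2 the plasmacytoid list was called lower (median -0.17, adjusted p = 0.020). Without SRBC library 1 the T cell, monocyte and neutrophil lists were called, and T cell and platelet lists were called with upper-quartile, quantile or TPM rescaling and the neutrophil list with TPM.

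The extremes of the table held sex-linked genes and small RNAs. Xist, the RNA that silences an X chromosome in female cells (chromosome X, 103460366 to 103483254), measured 0.210 and 0.327 after PBS and 339 and 306 after SRBC. The Y-linked genes Eif2s3y (31.4 and 38.4 after PBS), Kdm5d (21.1 and 29.3), Ddx3y (17.2 and 20.4) and Uty (3.57 and 5.70) stood at 0.113 or less in both SRBC libraries. Both PBS libraries thus showed a male pattern and both SRBC libraries a female pattern. The groups therefore differed in the sex pattern of these genes as well as in treatment, in 4 of 4 libraries. No change given here can be assigned to SRBC apart from sex. Mir703 and Scarna3a were listed at 0 in both PBS libraries and at 140 and 144, and 81.8 and 43.4, after SRBC, and in the authors' deposited table their q values were 0.317 and 0.556. Rnu11 (173 and 264, then 172 and 2.16) and the locus of Ccnd1 and Mir3962 (242 and 247, then 165 and 0) were called lower, and both calls were lost without SRBC library 2, with log2 fold changes of -0.31 and -0.57.

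Libraries of a group resembled each other more than those of different groups: Pearson's r across tested loci, which are not independent replicates, was 0.960 between the PBS and 0.978 between the SRBC libraries, against 0.912 to 0.926 between groups. Both SRBC libraries lay beyond both PBS libraries in 59.0% of tested loci. The 33.3% given by chance for interchangeable libraries is no test here. Loci are correlated, and summed FPKM was larger in both SRBC libraries. Of the tested loci, 1381 had in the authors' deposited table a q under 0.05, and 1319 of them were called here too. Another 852 loci were called by limma alone. The q-values carry no direction, so directions were not compared. Of the 33 lists 17 were called higher and 0 lower by camera (10 without SRBC library 2, and 10 with a stricter filter); none was called with an estimated correlation, where 1 list had an unadjusted p under 0.05. The stricter filter ended the calls of the interferon, class II, glycolysis, oxidative phosphorylation, ribosomal and cell cycle lists. Some lists held too few members for a test under that filter, so a call could also be lost in that way. Restriction to autosomes, chosen after seeing the data, ended the calls of glycolysis, ribosomal proteins and cell cycle. It also dropped loci whose names had no matched coordinates, Aldoa among them, so these losses cannot be put down to sex-linked genes. Leaving out loci listed at 0, also chosen then, ended the call of ribosomal proteins. Across the 4 rescalings the lowest medians were 0.71 for heme and iron, 0.41 for the unfolded protein response, 0.28 for heat shock, 0.26 for class I, 0.12 for cholesterol synthesis, 0.041 for glycolysis, 0.023 for macrophage markers, 0.0042 for cell cycle and -0.084 for interferon.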

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

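The tests of X dosage, sex, scaling factors, length, other cell types and PBS library 1 were chosen after the results were seen; the test of the lists after quantile normalization was set before its result was seen. Outside the main measurement, loci without a gene name were tested in a joint fit with the named loci. There 174 of 3610 unnamed loci were higher after SRBC than after PBS and 178 were lower. In the same fit 1005 higher and 316 lower calls fell among the 11020 named loci. Unnamed loci were thus not called more often in total, though a larger share of them was lower. No biological explanation was tested for the unnamed loci.

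Xist and the Y-linked genes separated the groups in all 4 libraries. X dosage as the source of the calls at large is argued against, since X-linked genes were not called more often than autosomal genes (18.1% and 20.1%; odds ratio 0.882, exact 95% interval 0.644 to 1.19, Fisher's exact test p = 0.466). Whether a sex difference between the mice contributes to autosomal changes cannot be told apart from the treatment, because the number of groups that held libraries of both patterns was 0. The effect of SRBC itself, which the design names, stays open beside it.

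Abundant genes were higher and scarce genes lower after SRBC, with median log2 fold changes from -0.15 in the lowest to 0.41 in the highest quintile of level. A single scaling factor per library is argued against by the opposite signs of those quintiles, which differed by 0.564. A factor shifts all levels in the same direction, though scarce ones less on the log2(FPKM + 1) scale. Transcript length is argued against by a difference that stayed at 0.52 or more within each of 5 classes of length. As the whole basis of the list calls the trend is argued against too, since 14 lists were called higher after quantile normalization, 12 of them among the 17 called as deposited, by camera at its preset correlation (with an estimated correlation none was called as deposited). Single loci were also called higher by limma in that setting, 18 of 25 NF-kB targets and 22 of 37 maturation genes. An effect of SRBC on abundant transcripts stays open, untested.

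Immediate early genes stood high in PBS library 1. Other cell types as carriers stay open. By a median log2 difference of 0.55, against -0.21 over all tested genes, PBS library 1 exceeded PBS library 2 in the markers pooled above. SRBC library 2 likewise held more of them than SRBC library 1 (0.45), but exceeded it by 0.126 in immediate early genes, where all tested genes differed by 0.15, which does not decide, as these cells may hold other transcripts after SRBC. PBS library 1 as the sole basis of all 9 lower calls is argued against by Dusp6, which measured 21.1 in PBS library 2 and 4.12 and 4.61 after SRBC. Without PBS library 1, 2 calls were kept, Dusp6 and Nr4a3. Nr4a3 was listed at 0 in both SRBC libraries, which can be a failed estimate, so its call is uncertain. For the other 7 that explanation stays open. Without PBS library 1 the log2 fold changes of these 7 ran from -0.70 to 0.028. Differences in handling time between mice may also have acted, and the labels give nothing to test that.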

How the results depend on the processing

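The restriction to autosomes and the handling of loci without a name or listed at 0 were chosen after seeing the data. Against 1488 higher, 683 lower and 17 called lists, the counts moved by over 1.5 times as follows. Without a filter on low values 16054 loci were tested, of which 751 were higher and 184 lower, and the cause was not tested. Upper-quartile rescaling gave 1417 lower, quantile normalization 922 higher, and TPM 629 higher and 1648 lower; the cause was not tested beyond the shift of the median. The 2-fold threshold gave 780 and 312 by construction. Leaving out each library in turn gave 746 to 1641 higher, 273 to 993 lower and 10 to 19 lists. The stricter filter, under which some lists held too few members for a test, gave 10 lists. Camera with an estimated correlation gave 0 and fry 1, and the cause was not tested. The gap between within-group and between-group correlations was 0.034 and moved to 0.038 with a pseudocount of 0.1 and 0.060 with the stricter filter.

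No named gene changed sign between the reported fit and a setting where either called it. Among lists called in the reported fit or the setting, medians changed sign for immediate early (0.28 to -0.33 without PBS library 2 and -0.15 with TPM), oxidative phosphorylation (-0.0095), ribosomal proteins (-0.18) and SIRPA-CD47 (-0.44) after quantile normalization, interferon (-0.084) and ribosomal proteins with TPM, cell cycle (-0.0023 without PBS library 1) and plasmacytoid markers (-0.17 without PBS library 2). Without PBS library 1 camera turned from down to up for plasmacytoid markers (0.40), and the immediate early median was 0.84. Medians of uncalled lists also changed sign; the cause was not tested. Of 133 called named genes 40 lost the call in at least 1 leave-one-out and 37 under at least 1 rescaling. With the replicate block 1684 were higher, 620 lower and 15 lists called; same-numbered libraries share only a number, their deviations correlating at 0.0516 over 2 pairs. On autosomes 1378 were higher and 640 lower, with loci at 0 left out 1552 and 755, and with unnamed loci included 1179 and 494. The estimated depth of 8680000 to 10300000 fragments limits what can be seen of genes near an FPKM of 1.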

Other observations

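The genes of this paragraph lie outside the naming rule and were chosen after their values were seen. Among transcription factors, Batf, an AP-1 partner of IRF4, measured 18.9 and 10.8 after PBS and 152 and 208 after SRBC (log2 fold change 3.54 ± 0.24 SE, limma adjusted p = 1.4e-12). Nab2, a corepressor of EGR proteins, measured 3.81 and 3.51 and then 44.1 and 54.2, and Rora, a nuclear receptor, 2.34 and 1.48 and then 30.0 and 21.5. Bcl2l11, which encodes the death-promoting protein BIM, measured 8.55 and 10.6 and then 70.7 and 72.7. Ptger4, a receptor of prostaglandin E2, measured 20.9 and 8.81 and then 108 and 123. Hhex, a homeobox gene (34.5 and 37.5, then 5.64 and 10.2), Bcl11a (67.8 and 75.9, then 21.5 and 24.6), and P2ry6, a nucleotide receptor (22.8 and 21.1, then 5.45 and 7.50), were lower. In contrast to Spic and Hmox1, Tfrc was lower, at 30.2 after PBS and 16.6 after SRBC.

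Beside Xist, 4 X-linked genes with Y-linked partners or relatives were higher after SRBC: Kdm5c (12.4 and 13.7, then 67.0 and 64.7), Eif2s3x (log2 fold change 1.21), Kdm6a (15.1 and 17.9, then 25.7 and 32.0) and Ddx3x (54.3 and 50.3, then 74.3 and 99.1), also chosen after their values were seen.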
